A study of Homo sapiens with 20 samples.

How the data were processed

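Total RNA from primary cultures of 5 normal human thyroids was measured on Affymetrix arrays, with 1 array for each of 4 treatments per thyroid (vehicle, IFN-gamma at 100 IU/ml, IL1-beta at 50 IU/ml, or the 2 together), 20 arrays in all. Per the labels' protocols, 5 micrograms of RNA were labelled as biotinylated cRNA, and incubation lasted 24 or 72 h. Thyroids 1 to 3 were measured on U133A arrays and thyroids 4 and 5 on U133A_2 arrays, which share 22277 probe sets. The deposited values are in log10 units of intensity, and per the README deposited with the authors' workbook each is the log10 of the intensity raised by 50, with negative sums set to 0, and raised by 50 again. The authors quantile-normalized the intensity values within each array type, the U133A_2 arrays to the first of them. For each treatment pair the authors deposited an unadjusted p-value of a 2-way ANOVA. For every pair except IL1-beta against IFN-gamma they also deposited a ratio, the fold change between treatment means. The values of all 20 arrays equal 1 column each of the workbook within 1e-08, and the treatment in the workbook equals the label for 20 of 20.

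The deposited log10 values were converted to log2 with no further normalization. Because of the 2 offsets, fold changes of dim genes are understated. Levels cannot be compared between the array types, so contrasts were taken within thyroids. The 62 control probe sets were left out, as were 50 probe sets of sex-linked genes that could bear on a donor's identity. Of the others, 20641 have exactly 1 gene symbol, 484 have several and 1090 have none. Symbols were updated through the gene number with the gene table of assembly GRCh38.p14 for 20345 probe sets and kept for 296. Each of the 12790 genes was represented by the probe set with the highest mean over all arrays (4693 genes have more than 1), with no filter on dim genes. Arrays have no count depth, and their number limits the precision.

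A linear model with treatment and thyroid as factors was fitted with limma 3.58.1 in R 4.3.3, with 12 residual and 3.49 prior degrees of freedom. The 6 contrasts were tested, all two-sided: each cytokine and their combination against vehicle, the combination against each cytokine, and the interaction, which is the combination's log2 change minus the sum of the 2 single changes. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05. Each array's deviations from the mean of its treatment and array type correlated across genes between arrays of the same thyroid (0.331 to 0.631), which the thyroid term takes up. For thyroids 4 and 5, the only ones of their array type, these correlations are the same by construction. On simulated data of the same size, with 200 of 12790 genes changed, 37.1 to 48.4% of 1.5-fold, 89.9 to 91.3% of 2-fold and 98.6 to 100% of 4-fold changes were recovered for the 5 treatment contrasts, with 6 to 11 false calls. For the interaction these shares were 12.9, 69.6 and 91.3%, with 9 false calls.

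The 29 gene lists were tested in 6 contrasts (174 tests) with camera at a preset correlation of 0.01, and again with the correlation estimated for each list. Adjustment was over the lists of a contrast. Their subjects are MHC class I, MHC class II, immunoproteasome, constitutive proteasome, IFN-gamma signalling and its targets, type I interferon, chemokines, NF-kB, cytokines, complement, adhesion and costimulation, and thyroid function. Others hold death receptors and caspases, the BCL2 family, epithelial junctions, matrix proteases, cell cycle, unfolded protein response, oxidative stress, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation and the TGF-beta family. The rest are markers of fibroblasts, endothelium, T and natural killer cells, B and plasma cells, macrophages and dendritic cells, and C cells.

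The lists, the contrasts, the test and its threshold were chosen before the data were examined, as was the rule for naming genes. The rule took the 10 largest rises and 10 largest falls of each contrast with vehicle, and 6 and 6 of the others, among genes called and changed the same way in all thyroids. It added up to 4 members with the smallest p of each list described, and 39 genes fixed in advance. From these, examples were taken, and results of 4 genes that the rule names are not given.

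Alternatives were run without the thyroid term (array type as covariate), with thyroid as a random block, without each thyroid in turn, on each array type alone, with quantile or median normalization over all arrays, and with offsets of 16 and 100. Further ones left out the dimmest 25% or 50% of genes, used all 22165 probe sets or the mean per gene, a plain 2-way ANOVA, only the groups of a contrast, array weights, trended robust moderation, a fold of at least 1.5, an adjusted p under 0.01, and fry for the lists. Runs without the vehicle array of thyroid 2, without the IL1-beta array of thyroid 4 and without both were added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.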

Results

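Gene expression was measured in primary cells from 5 normal human thyroids, each divided over 4 cultures that received vehicle, 100 IU/ml of interferon-gamma (IFN-gamma), 50 IU/ml of interleukin-1 beta (IL1-beta) or both cytokines. IFN-gamma is secreted mainly by T and natural killer cells, and IL1-beta is secreted mainly by macrophages and signals through NF-kB. The cultures lasted 24 or 72 h, and the sources used here do not say which time belongs to which culture. Each culture was hybridised to its own array, 12 arrays of type U133A for thyroids 1 to 3 and 8 of type U133A_2 for thyroids 4 and 5, so that every treatment had 5 arrays. The median signal was 334 to 335 intensity units on the U133A arrays and 274 on the U133A_2 arrays, and 2.15 to 2.30% and 1.19 to 1.22% of probe sets lay at the lowest possible value. In all, 12790 genes were tested, and the number of arrays limits the precision.

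Each change given is the mean of the 5 within-thyroid differences on the log2 scale, with ± for their SD (n = 5), and adjusted p-values are from limma. Counts of genes that rose or fell rest on an adjusted p under 0.05 alone. A gene named as having risen or fallen also moved that way in all 5 thyroids, unless a smaller number of thyroids is given. With each thyroid's mean removed, the first principal component held 41.3% of the variance and ran from the vehicle arrays to the arrays with both cytokines, and the second held 19.4% and separated IFN-gamma from IL1-beta.

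**Figure D1:**
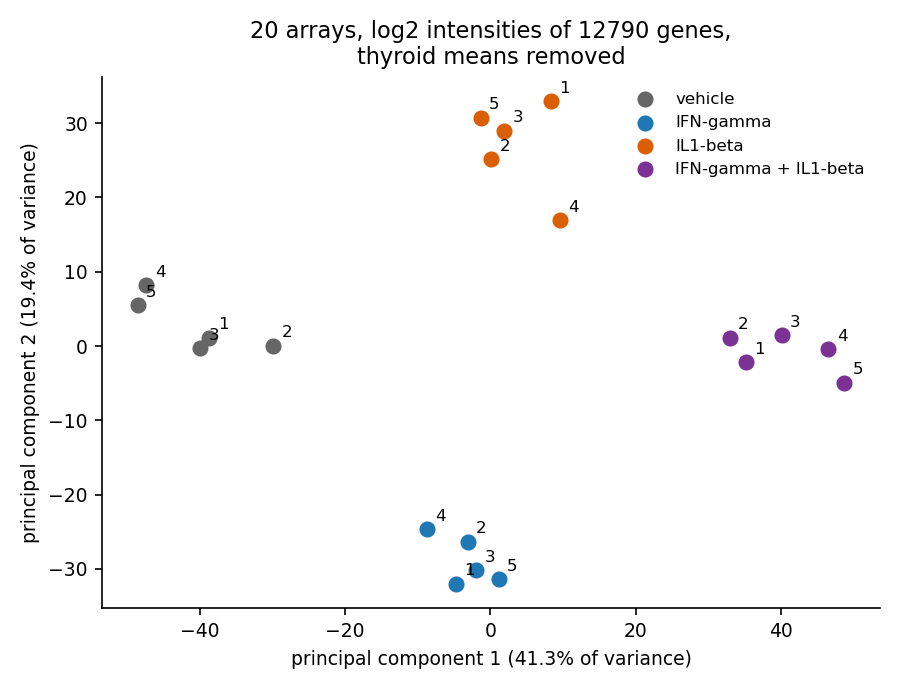
Principal components of all 20 arrays after the mean of each thyroid was removed, with 1 point per array, coloured by treatment and marked with the thyroid's number. The x axis (component 1, 41.3% of the variance) parts vehicle from both cytokines and the y axis (component 2, 19.4%) parts IFN-gamma from IL1-beta, with the IL1-beta array of thyroid 4 nearest to the other groups.

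IFN-gamma alone raised IDO1, which degrades tryptophan, more than any other gene that passed in all 5 thyroids, by 6.91 ± 0.81 (adjusted p = 1.11e-06). Its mean log2 level went from 8.81 to 15.60 on the U133A arrays and from 8.21 to 15.29 on the U133A_2 arrays. The T cell attracting chemokines CXCL9, CXCL10 and CXCL11 rose by 6.43 ± 1.74, 5.34 ± 1.86 and 5.03 ± 2.01 (adjusted p = 0.000251, 0.000331 and 0.000556). The transcription factor IRF1 rose by 4.52 ± 0.69 (adjusted p = 2.01e-08). The largest falls were those of LRRN3 (-2.59 ± 0.57, adjusted p = 4.57e-05) and the aldo-keto reductase AKR1C3 (-2.30 ± 0.37, adjusted p = 0.000112). KIF20A, a mitotic kinesin, fell by 1.94 ± 1.84 (adjusted p = 0.0204), which did not pass without thyroid 1 (-1.73, adjusted p = 0.0960) or thyroid 5 (-1.23, adjusted p = 0.0900).

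Antigen presentation genes rose with IFN-gamma. Of the 18 MHC class II genes measured, 16 rose and 2 did not pass (17 rose adjusted over the list alone). Their median change was 2.48, with a camera adjusted p = 4.90e-22, or adjusted p = 0.0162 with an estimated correlation. Among them were the class II transactivator CIITA (3.13 ± 1.20, adjusted p = 7.56e-05), the invariant chain CD74 (2.66 ± 0.69, adjusted p = 3.05e-05), HLA-DRA (3.18 ± 1.41, adjusted p = 0.00243) and the lysosomal thiol reductase IFI30 (4.00 ± 0.96, adjusted p = 3.32e-05). Of the 16 MHC class I genes, 13 rose and 3 did not pass (14 rose adjusted over the list alone). For this list the camera adjusted p = 6.35e-14 became adjusted p = 0.0843 with an estimated correlation. The peptide transporter TAP1 led them with 4.61 ± 1.28 (adjusted p = 1.44e-05), and HLA-E rose by 2.20 ± 0.86 (adjusted p = 6.55e-05). All 6 members of the immunoproteasome list rose, also adjusted over the list alone, among them PSMB9 (4.35 ± 1.83, adjusted p = 0.000128) and PSMB10 (3.06 ± 0.57, adjusted p = 1.02e-06). That list had a camera adjusted p = 1.02e-11 and adjusted p = 0.0249 with an estimated correlation.

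Interferon-regulated genes followed the same direction. Among the 37 IFN-gamma signalling genes and targets, 32 rose and 5 did not pass (32 rose and 1 fell adjusted over the list alone), with a median of 2.04, a camera adjusted p = 6.73e-37 and adjusted p = 0.0189 with an estimated correlation. APOL3 rose by 3.65 ± 0.47 (adjusted p = 1.02e-06) and GBP2 by 4.46 ± 0.79 (adjusted p = 1.04e-06), while the receptor chain IFNGR1 did not pass (0.00 ± 0.40, adjusted p = 0.998). Of the 29 type I interferon antiviral genes, 28 rose and 1 did not pass (29 rose adjusted over the list alone). ISG20 rose by 3.77 ± 1.26 (adjusted p = 6.82e-05) and DDX60 by 3.53 ± 1.67 (adjusted p = 0.000288). Their camera adjusted p = 2.68e-24 became adjusted p = 0.129 with an estimated correlation, and their median change was 0.43 in thyroid 2 against 2.78 to 4.38 in the other thyroids. The vehicle array of thyroid 2 already stood 3.66 above the mean of the vehicle arrays of thyroids 1 and 3 on this list. The counts of risen genes in the 5 lists of antigen presentation and interferon response were the same without that array. Runs without it kept the IL1-beta array of thyroid 2, which was high too. Their counts, here and below, are therefore not cleaner estimates.

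Inflammatory genes were examined in 5 lists. Of 21 chemokines, 4 rose, 1 fell and 16 did not pass (the same counts adjusted over the list alone), with a camera adjusted p = 0.00605 and adjusted p = 0.400 with an estimated correlation. CX3CL1 rose by 1.93 ± 0.75 (adjusted p = 0.00121), whereas CXCL12 fell by 1.79 ± 0.70 (adjusted p = 0.00352) and CCL20 did not pass (-0.07 ± 0.74, adjusted p = 0.969). Of 29 NF-kB pathway genes, 9 rose and 20 did not pass (12 rose adjusted over the list alone, and 12 rose without the thyroid 2 vehicle array), led by the kinase RIPK2 (2.22 ± 0.24, adjusted p = 4.22e-07). Of 26 cytokines and inflammatory effectors, 7 rose and 19 did not pass (8 rose adjusted over the list alone). IL32 rose by 3.80 ± 0.62 (adjusted p = 0.000198) and IL6 by 1.55 ± 0.57 (adjusted p = 0.00782), the latter not passing without thyroid 5 (1.31, adjusted p = 0.0708). Of 12 complement genes, 6 rose and 6 did not pass, over all genes and adjusted over the list alone, with SERPING1 first (3.53 ± 0.85, adjusted p = 5.69e-06). The camera adjusted p was 5.66e-06, 0.000962 and 0.00135 for these 3 lists, and adjusted p = 0.279, 0.0843 and 0.168 with an estimated correlation. Of 17 adhesion and costimulation genes, 6 rose, 4 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.0817, or 0.0484 without thyroid 2). ICAM1 rose by 3.81 ± 1.18 (adjusted p = 1.59e-05) and the checkpoint ligand PDCD1LG2 by 2.99 ± 0.67 (adjusted p = 9.95e-06).

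Among genes of thyroid function, 5 of 20 fell with IFN-gamma and 15 did not pass, also adjusted over the list alone (camera adjusted p = 0.0669, or 0.0378 without thyroid 5). Thyroglobulin, TG, fell by 1.03 ± 0.66 (adjusted p = 0.00820) and the thyrotropin receptor, TSHR, by 0.65 ± 0.33 (adjusted p = 0.0244). TG did not pass without thyroid 2 (-0.86, adjusted p = 0.0502) or thyroid 3 (-0.96, adjusted p = 0.0568), nor on the U133A_2 arrays alone (-0.36, adjusted p = 0.461, against -1.48 on U133A). TSHR did not pass without thyroid 1, 3, 4 or 5 (adjusted p = 0.110, 0.0571, 0.0559 and 0.0527). The iodide transporter SLC5A5 (-0.13 ± 0.31, adjusted p = 0.666) and PAX8 (-0.12 ± 0.15, adjusted p = 0.639) did not pass.

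Death receptors, ligands and caspases rose with IFN-gamma in 10 of 23 cases, fell in 1 and did not pass in 12 (11 rose and 3 fell adjusted over the list alone), with a camera adjusted p = 0.000236 and adjusted p = 0.0189 with an estimated correlation. FAS rose by 1.13 ± 0.37 (adjusted p = 0.000119) and the death ligand TNFSF10 by 2.70 ± 1.07 (adjusted p = 0.000570). Of 17 genes of the BCL2 family, inhibitors of apoptosis and the apoptosome, 3 rose, 2 fell and 12 did not pass (4 rose and 3 fell adjusted over the list alone). Their median and mean were -0.10 and -0.02 although the camera test pointed upward (adjusted p = 0.586), and PMAIP1 rose by 1.36 ± 0.39 (adjusted p = 1.93e-05). Cell cycle genes fell in 13 of 33 cases (21 adjusted over the list alone, 16 without the thyroid 2 vehicle array and 11 without it and the thyroid 4 IL1-beta array), with none rising and a median of -0.85. Their camera adjusted p = 2.03e-06 became adjusted p = 0.400 with an estimated correlation, and CCNB2 fell by 1.27 ± 0.85 (adjusted p = 0.0114). Of 21 epithelial junction and keratin genes, 2 fell and 19 did not pass, also adjusted over the list alone (camera adjusted p = 0.538). Desmoplakin, DSP, fell by 0.47 ± 0.16 (adjusted p = 0.00485). Of 22 matrix proteases and inhibitors, PLAUR was the 1 gene that rose (1.13 ± 0.69 in 4 of 5 thyroids, adjusted p = 0.00455), also adjusted over the list alone (median -0.06, mean 0.01, camera adjusted p = 0.662).

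Over all genes, IFN-gamma changed 1817, of which 793 rose and 1024 fell, and 1666 of them moved the same way in all 5 thyroids. At least 2-fold changes numbered 254 upward and 118 downward. The count was 1073 without thyroid 3, 1203 without thyroid 4 and 1068 without thyroid 5.

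**Figure D2:**
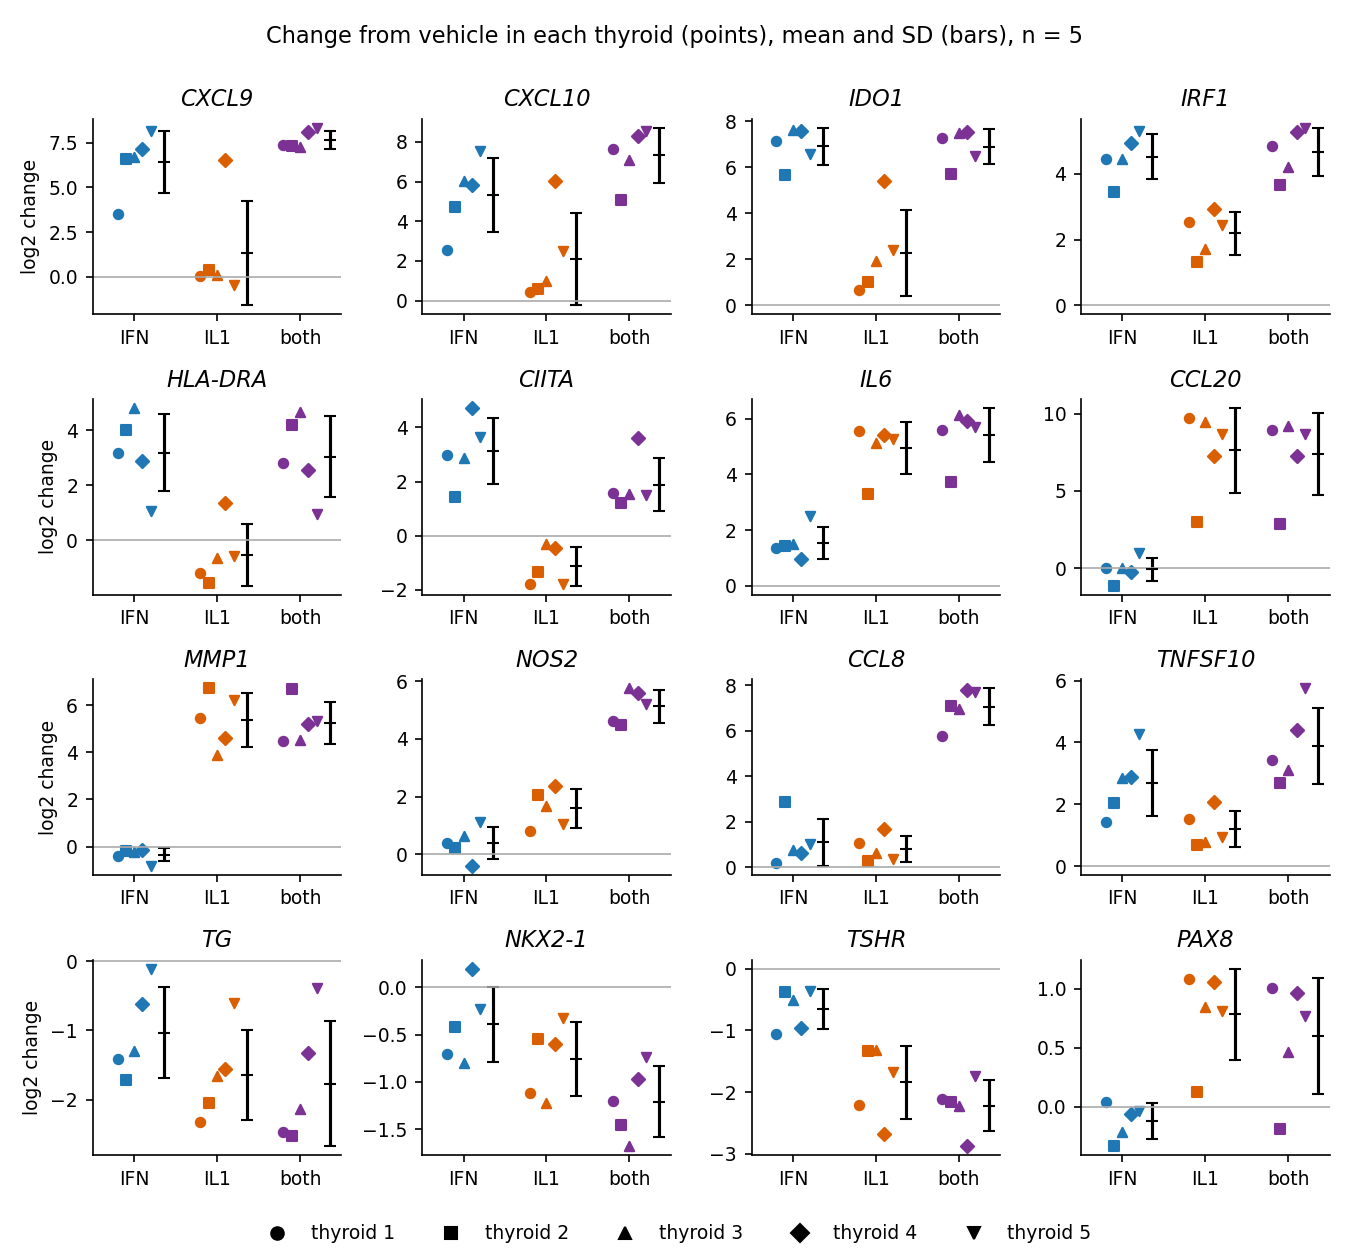
Log2 change against the vehicle array of the same thyroid for 16 genes under each treatment, with 1 point per thyroid and bars for the mean and SD of 5 thyroids. CXCL9, CXCL10, IDO1 and HLA-DRA rose with IFN-gamma, IL6, CCL20 and MMP1 rose with IL1-beta and with both, NOS2 and CCL8 stood highest with both, and TG and TSHR lay below 0 on average under every treatment.

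IL1-beta alone raised a different leading set. CCL20, a chemokine for CCR6-bearing lymphocytes and dendritic cells, rose by 7.62 ± 2.74 (adjusted p = 1.72e-05), from a mean log2 level of 7.80 to 15.20 on the U133A arrays and from 6.86 to 14.81 on the U133A_2 arrays. Its mean vehicle levels lay under the array medians (8.76 and 8.55), where the offset understates a change. The rise was 3.03 in thyroid 2 and 7.24 to 9.70 in the others. In thyroids 1 and 3 the CCL20 change with IFN-gamma was exactly 0, which can mean that vehicle and IFN-gamma arrays lay at the lowest possible value. Rises from those arrays are then lower bounds. TNFAIP6, which binds hyaluronan, rose by 5.56 ± 1.56 (adjusted p = 4.72e-06), and the matrix metalloproteinases MMP3 and MMP1 rose by 5.51 ± 1.14 and 5.37 ± 1.16 (adjusted p = 8.75e-06 and 4.93e-07). IL6 rose by 4.93 ± 0.94 (adjusted p = 5.86e-07). The largest falls were those of the transcriptional inhibitor ID3 (-3.06 ± 1.21, adjusted p = 0.00126) and of FCGBP (-2.91 ± 0.51, adjusted p = 2.00e-05), and the sodium channel subunit SCNN1A fell by 2.30 ± 0.25 (adjusted p = 6.75e-06).

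Inflammatory lists led with IL1-beta. Of 26 cytokines and inflammatory effectors, 20 rose, 1 fell and 5 did not pass, also adjusted over the list alone, with a median of 1.81, a camera adjusted p = 3.96e-18 and adjusted p = 0.000403 with an estimated correlation. SOD2 rose by 3.87 ± 1.51 (adjusted p = 4.09e-05) and LIF by 1.64 ± 0.37 (adjusted p = 1.32e-05). Of 21 chemokines, 13 rose and 8 did not pass (14 rose adjusted over the list alone), with a camera adjusted p = 4.08e-16 and adjusted p = 0.0209 with an estimated correlation. Among them CXCL3 rose by 5.22 ± 1.10 (adjusted p = 8.26e-08) and CCL2 by 5.35 ± 1.31 (adjusted p = 9.59e-06), whereas CXCL9 (1.33 ± 2.92, adjusted p = 0.373) and CXCL10 (2.09 ± 2.33, adjusted p = 0.0847) did not pass. Of 29 NF-kB pathway genes, 19 rose, 1 fell and 9 did not pass (22 rose and 1 fell adjusted over the list alone), with a camera adjusted p = 4.98e-19 and adjusted p = 0.0412 with an estimated correlation. BIRC3 rose by 3.81 ± 1.07 (adjusted p = 4.72e-06), NFKB1 by 2.14 ± 0.47 (adjusted p = 3.82e-06) and the inhibitor NFKBIA by 2.82 ± 1.33 (adjusted p = 0.000218).

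Matrix and adhesion genes also rose with IL1-beta. Of 22 matrix proteases and inhibitors, 12 rose, 1 fell and 9 did not pass (12 rose and 3 fell adjusted over the list alone), with a camera adjusted p = 2.63e-06 and adjusted p = 0.0209 with an estimated correlation. MMP10 rose by 3.46 ± 0.92 (adjusted p = 5.93e-05). Of 17 adhesion and costimulation genes, 8 rose, 2 fell and 7 did not pass (10 rose and 3 fell adjusted over the list alone), with a camera adjusted p = 7.72e-05 and adjusted p = 0.0636 with an estimated correlation. ICAM1 rose by 3.32 ± 1.37 (adjusted p = 4.15e-05) and CD40 by 1.67 ± 0.56 (adjusted p = 1.85e-05). Of 12 complement genes, 3 rose, 1 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.109, or 0.00828 without thyroid 2). C3 rose by 4.47 ± 2.79 in 4 of 5 thyroids (adjusted p = 0.00140) and CFB by 3.20 ± 2.03 (adjusted p = 0.00138).

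Interferon-regulated genes depended on 2 arrays in this comparison. Of 29 type I interferon antiviral genes, 5 rose (19 adjusted over the list alone) and 24 did not pass. The count was 22 without the vehicle array of thyroid 2, 1 without the IL1-beta array of thyroid 4 and 16 without both arrays. Leaving out that vehicle array kept the IL1-beta array of thyroid 2, which was also high. In thyroid 2 the list's median changed by 0.05 with IL1-beta and by 0.32 when IFN-gamma was added. Runs without the vehicle array thus place IL1-beta near the IFN-gamma level there, and their counts, here and below, are not cleaner estimates. The list's median was 3.77 in thyroid 4 and 0.05 to 1.48 in the others, its camera adjusted p was 2.85e-08, and adjusted p = 0.387 with an estimated correlation. Of 16 MHC class I genes, 9 rose (12 adjusted over the list alone) and 7 did not pass, and the 3 counts without these arrays were 13, 2 and 12. ERAP1 rose by 1.41 ± 0.73 (adjusted p = 0.000937), while TAP1 (1.55 ± 1.38, adjusted p = 0.0308) did not pass without the thyroid 4 array (1.10, adjusted p = 0.0925) or without thyroid 1, 3, 4 or 5 (adjusted p = 0.0737, 0.0664, 0.179 and 0.123). All 6 immunoproteasome genes rose, also adjusted over the list alone (5 without the thyroid 4 array), with PSMB10 up by 2.04 ± 0.78 (adjusted p = 1.85e-05). Of the 37 IFN-gamma signalling genes and targets, 19 rose (24 adjusted over the list alone) and 18 did not pass, and the counts without these arrays were 25, 12 and 23. IRF1 rose by 2.19 ± 0.66 (adjusted p = 1.41e-05). The camera adjusted p of these 3 lists was 2.63e-06, 7.40e-07 and 1.13e-11, and adjusted p = 0.238, 0.0636 and 0.137 with an estimated correlation.

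MHC class II genes did not follow. Cathepsin S, CTSS, was the 1 gene of 18 that rose (3.26 ± 1.27, adjusted p = 4.32e-05), 17 did not pass, also adjusted over the list alone, and the camera adjusted p was 0.889, the list's median being -0.24 and its mean 0.02. Without the thyroid 4 IL1-beta array, 2 class II genes fell. CIITA did not pass (-1.13 ± 0.71, adjusted p = 0.0595) but fell without thyroid 4 (-1.30, adjusted p = 0.0378).

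Some genes of thyroid function also changed with IL1-beta. TSHR fell by 1.84 ± 0.59 (adjusted p = 9.24e-06), TG by 1.64 ± 0.66 (adjusted p = 0.000241) and the transcription factor HHEX by 1.23 ± 0.55 (adjusted p = 0.000535). On the U133A_2 arrays alone TG did not pass (-1.08, adjusted p = 0.0823). Of the 20 genes of that list, 6 fell, 2 rose and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.0535, or 0.0444 without thyroid 4 and 0.0282 without thyroid 5). PAX8 rose by 0.78 ± 0.39 (adjusted p = 0.00162), NKX2-1 fell by 0.76 ± 0.39 (adjusted p = 0.00282) and SLC5A5 did not pass (0.23 ± 0.29, adjusted p = 0.380). Of 21 epithelial junction and keratin genes, 6 fell, 1 rose and 14 did not pass (7 fell and 1 rose adjusted over the list alone), with a camera adjusted p = 0.00209 and adjusted p = 0.0636 with an estimated correlation. E-cadherin, CDH1, fell by 2.18 ± 0.95 (adjusted p = 0.000117), whereas claudin-1, CLDN1, rose by 1.44 ± 0.58 (adjusted p = 0.000353).

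Of the 23 death receptors, ligands and caspases, 8 rose, 2 fell and 13 did not pass with IL1-beta (11 rose and 3 fell adjusted over the list alone), with a camera adjusted p = 0.000431 and adjusted p = 0.0209 with an estimated correlation. The decoy receptor TNFRSF11B rose by 2.10 ± 0.70 (adjusted p = 1.66e-05), FAS by 0.73 ± 0.36 (adjusted p = 0.00278), and CASP6 fell by 0.83 ± 0.19 (adjusted p = 0.00231). TNFSF10 did not pass (1.20 ± 0.59, adjusted p = 0.0676), but passed without thyroid 5 (1.26, adjusted p = 0.0208). In the BCL2 family list, 4 of 17 rose, 1 fell and 12 did not pass, also adjusted over the list alone. Its camera adjusted p = 0.00564 became adjusted p = 0.0636 with an estimated correlation, and the anti-apoptotic BCL2A1 and the pro-apoptotic BID rose by 4.17 ± 0.50 (adjusted p = 3.91e-07) and 2.13 ± 0.46 (adjusted p = 8.75e-06). Of 33 cell cycle genes, 5 fell and 28 did not pass, also adjusted over the list alone (2 fell without the thyroid 4 IL1-beta array), with a camera adjusted p = 8.92e-06 and adjusted p = 0.387 with an estimated correlation. MCM5 fell by 1.10 ± 0.29 (adjusted p = 0.0163), which did not pass without thyroid 3 (-1.14, adjusted p = 0.0624) or thyroid 5 (-0.99, adjusted p = 0.0511).

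IL1-beta changed 1952 genes, 888 upward and 1064 downward, of which 1808 moved the same way in all thyroids. At least 2-fold changes numbered 295 upward and 171 downward. The count was 1110 without thyroid 3 and 1276 without thyroid 4.

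With both cytokines, the ubiquitin-like modifier UBD and CXCL9 rose most, by 7.68 ± 0.92 and 7.68 ± 0.50 (adjusted p = 2.47e-06 and 9.81e-06), both from vehicle levels under the array medians. CCL20 rose by 7.39 ± 2.63 (adjusted p = 4.16e-06), the monocyte chemokine CCL8 by 7.05 ± 0.82 (adjusted p = 2.66e-08) and IDO1 by 6.89 ± 0.78 (adjusted p = 1.55e-07). SERPINB7, a protease inhibitor, rose by 5.78 ± 0.76 (adjusted p = 8.23e-10). The largest falls were those of the transcript FLJ14054 (-3.64 ± 0.78, adjusted p = 1.04e-06) and of FCGBP (-3.44 ± 0.58, adjusted p = 7.43e-07), and cadherin-6, CDH6, fell by 3.16 ± 0.43 (adjusted p = 4.00e-07).

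Inflammatory and interferon programmes were both present with the combination. Of 21 chemokines, 18 rose and 3 did not pass, also adjusted over the list alone, with a median of 4.26, a camera adjusted p = 2.12e-15 and adjusted p = 0.0306 with an estimated correlation. CCL7 rose by 5.73 ± 1.02 (adjusted p = 2.54e-07) and CXCL10 by 7.33 ± 1.39 (adjusted p = 3.56e-06). Of 26 cytokines and inflammatory effectors, 24 rose, 1 fell and 1 did not pass, also adjusted over the list alone, with a camera adjusted p = 7.21e-16 and adjusted p = 0.000858 with an estimated correlation. Inducible nitric oxide synthase, NOS2, rose by 5.13 ± 0.57 (adjusted p = 3.70e-08) and IL1A by 3.83 ± 1.25 (adjusted p = 3.16e-07). Of 29 NF-kB pathway genes, 23 rose and 6 did not pass (26 rose adjusted over the list alone), with RIPK2 up by 3.67 ± 0.18 (adjusted p = 4.71e-10) and TRAF1 by 3.62 ± 0.27 (adjusted p = 3.78e-08). Its camera adjusted p = 4.95e-18 became adjusted p = 0.0502 with an estimated correlation. Of 12 complement genes, 8 rose, 1 fell and 3 did not pass (9 rose and 1 fell adjusted over the list alone), with CFB up by 5.53 ± 1.91 (adjusted p = 2.88e-06). Of 17 adhesion and costimulation genes, 11 rose, 3 fell and 3 did not pass (12 rose and 4 fell adjusted over the list alone). ICAM1 rose by 5.70 ± 1.21 (adjusted p = 6.93e-08) and IL15RA by 4.71 ± 1.07 (adjusted p = 4.36e-08). The camera adjusted p of these last 2 lists was 0.000155 and 5.63e-05, and adjusted p = 0.0891 and 0.0638 with an estimated correlation.

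All 29 type I interferon antiviral genes rose with both cytokines, also adjusted over the list alone, with a median of 3.31. In thyroid 2 the list's median change was 0.37, against 3.298 to 4.885 in the other thyroids. Among 37 IFN-gamma signalling genes and targets, 34 rose and 3 did not pass (35 rose adjusted over the list alone), and IRF1 rose by 4.67 ± 0.74 (adjusted p = 4.15e-09). MHC class II genes rose in 16 of 18 cases and 2 did not pass, also adjusted over the list alone, with CTSS up by 4.76 ± 1.28 (adjusted p = 2.83e-07) and HLA-DRA by 3.03 ± 1.47 (adjusted p = 0.000980). MHC class I genes rose in 13 of 16 cases, fell in 1 and did not pass in 2 (14 rose and 1 fell adjusted over the list alone), and all 6 immunoproteasome genes rose, also adjusted over the list alone. TAP1 rose by 4.56 ± 1.26 (adjusted p = 2.09e-06) and PSMB10 by 3.14 ± 0.68 (adjusted p = 7.95e-08). The camera adjusted p of these 5 lists was 2.53e-17, 2.71e-25, 5.38e-10, 1.02e-08 and 3.34e-07, and adjusted p = 0.138, 0.0483, 0.0502, 0.133 and 0.0651 with an estimated correlation. The counts of risen genes moved by at most 1 without the thyroid 2 vehicle array or the thyroid 4 IL1-beta array.

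TSHR fell by 2.22 ± 0.41 with both cytokines (adjusted p = 3.02e-07), TG by 1.77 ± 0.91 (adjusted p = 3.24e-05), FOXE1 by 1.32 ± 0.32 (adjusted p = 5.84e-07) and NKX2-1 by 1.21 ± 0.38 (adjusted p = 1.78e-05). The fall of TG was larger on the U133A arrays (-2.38) than on the U133A_2 arrays (-0.86, adjusted p of the difference = 0.0380), where it did not pass on its own (adjusted p = 0.0631). In the list of thyroid function, 8 of 20 fell, 2 rose and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.127). PAX8 rose by 0.60 ± 0.49 in 4 of 5 thyroids (adjusted p = 0.00403) and SLC5A5 did not pass (0.20 ± 0.49, adjusted p = 0.377). Epithelial junction and keratin genes fell in 9 of 21 cases, rose in 1 and did not pass in 11, also adjusted over the list alone. Their camera adjusted p = 0.0343 became adjusted p = 0.133 with an estimated correlation and 0.0533, 0.0732 and 0.0675 without thyroid 1, 2 or 3. CDH1 fell by 2.48 ± 0.47 (adjusted p = 8.65e-06). Of 22 matrix proteases and inhibitors, 7 rose, 2 fell and 13 did not pass, also adjusted over the list alone. MMP1 rose by 5.25 ± 0.88 (adjusted p = 1.11e-07), and the list's camera adjusted p = 0.00679 became adjusted p = 0.0891 with an estimated correlation.

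Cell cycle genes fell in 27 of 33 cases with both cytokines and 6 did not pass (28 fell adjusted over the list alone, and 23 fell without the thyroid 2 vehicle and thyroid 4 IL1-beta arrays), with a median of -1.27. CCNB2 fell by 2.34 ± 0.91 (adjusted p = 2.78e-05) and TOP2A by 2.26 ± 1.17 (adjusted p = 0.000184), and the list's camera adjusted p = 5.75e-09 became adjusted p = 0.248 with an estimated correlation. Of 23 death receptors, ligands and caspases, 13 rose, 2 fell and 8 did not pass (13 rose and 3 fell adjusted over the list alone), with a camera adjusted p = 9.60e-06 and adjusted p = 0.00835 with an estimated correlation. TNFSF10 rose by 3.88 ± 1.22 (adjusted p = 4.26e-06), FAS by 1.25 ± 0.50 (adjusted p = 8.60e-06), CASP10 by 1.60 ± 0.30 (adjusted p = 6.40e-08) and CASP1 by 2.34 ± 0.91 (adjusted p = 3.25e-05). In the BCL2 family list, 8 of 17 rose, 3 fell and 6 did not pass, also adjusted over the list alone. Its camera adjusted p = 0.0111 became adjusted p = 0.0844 with an estimated correlation. BID rose by 2.28 ± 0.56 (adjusted p = 7.31e-07), and BCL2 itself did not pass (0.19 ± 0.27, adjusted p = 0.421).

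The combination changed 4455 genes, 1784 upward and 2671 downward, of which 3819 moved the same way in all thyroids. At least 2-fold changes numbered 625 upward and 559 downward. By a test chosen after the data were seen, the change differed between the array types for 91 genes, among them TG and IL15RA, whose rise was 3.96 on U133A and 5.83 on U133A_2 arrays (adjusted p of the difference = 0.0449). The count stayed between 3411 and 4153 when 1 thyroid was left out.

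**Figure D3:**
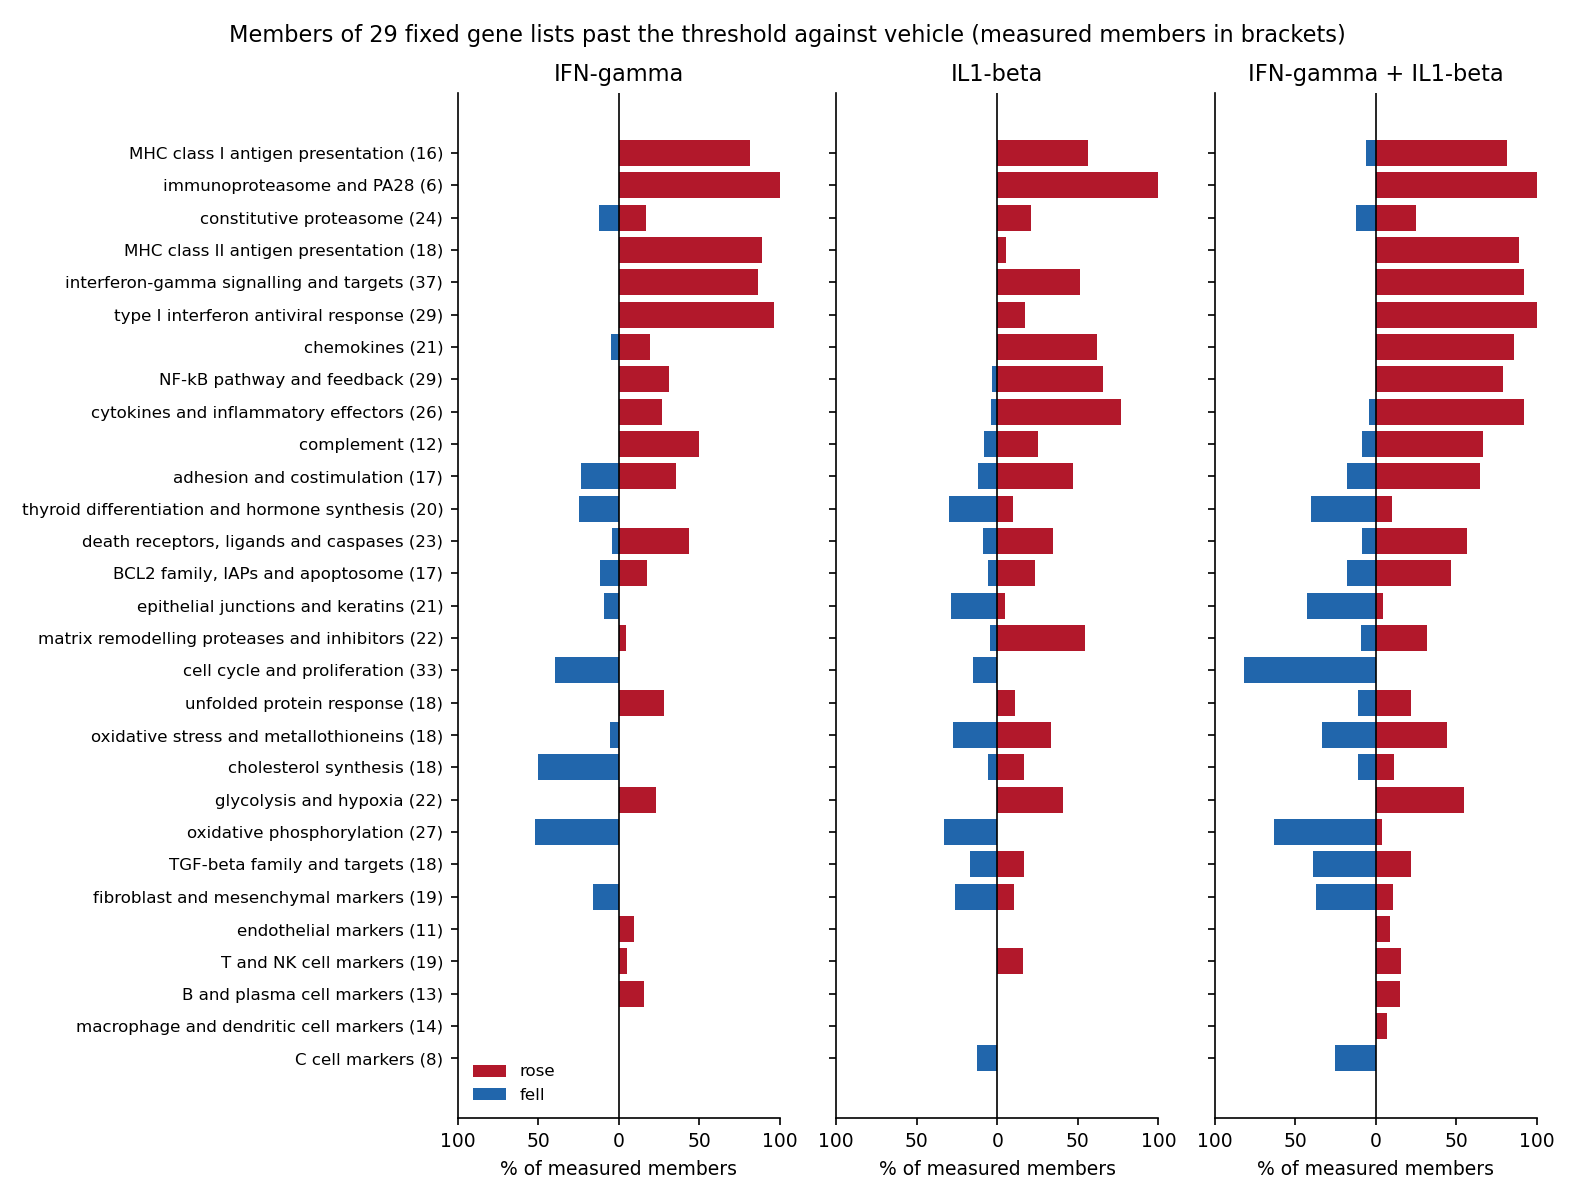
Percent of measured members that rose (right of 0) or fell (left of 0) in each of 29 gene lists under IFN-gamma, IL1-beta and both cytokines, with 1 bar per list and treatment. Type I interferon and MHC class II genes rose mainly under IFN-gamma and both, chemokines and cytokines under IL1-beta and both, and cell cycle genes fell in 13, 5 and 27 of 33 cases.

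**Figure D4:**
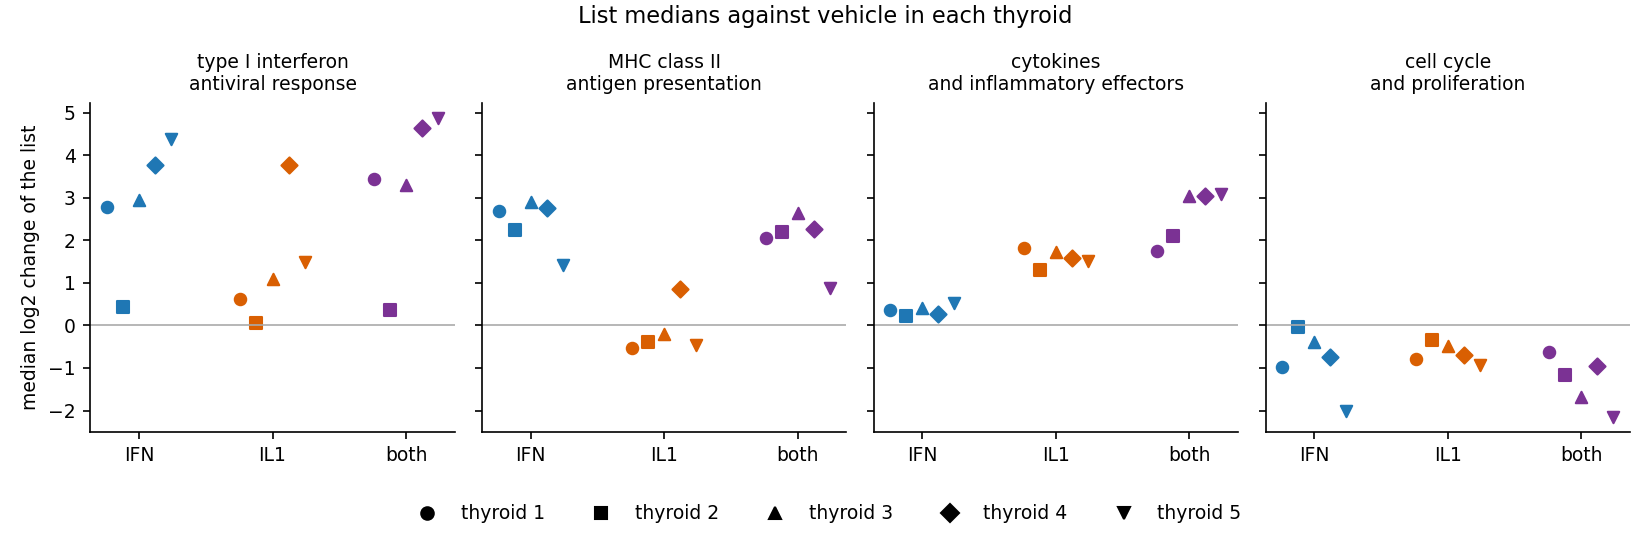
Median log2 change of 4 gene lists in each thyroid under each treatment, with 1 point per thyroid. The type I interferon list changed in thyroid 2 by 0.43 with IFN-gamma and by 0.37 with both, and in thyroid 4 by 3.77 with IL1-beta. Each of these values lay outside the range of the other thyroids.

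What each cytokine adds to the other was asked by comparing the combination with each cytokine alone. Adding IL1-beta to IFN-gamma raised CCL20 by 7.46 ± 2.08 (adjusted p = 1.73e-05), SERPINB7 by 6.10 ± 0.74 (adjusted p = 5.58e-10) and CCL8 by 5.95 ± 1.14 (adjusted p = 3.96e-07). The CCL20 rise may be a lower bound, since the IFN-gamma arrays of thyroids 1 and 3 held the same CCL20 value as vehicle, possibly the lowest one. GFRA2, a receptor for neurturin, fell by 2.52 ± 0.53 (adjusted p = 7.52e-06) and TSHR by 1.57 ± 0.35 (adjusted p = 3.41e-05). Chemokines rose in 14 of 21 cases (17 adjusted over the list alone), NF-kB pathway genes in 21 of 29 (24) and cytokines in 19 of 26 (20, with 1 falling), and no member of these lists fell over all genes. Their camera adjusted p was 8.65e-18, 6.80e-21 and 8.83e-18, and adjusted p = 0.0245, 0.0385 and 0.000467 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 18 cases (12 rose and 1 fell adjusted over the list alone), with a camera adjusted p = 5.88e-06 and adjusted p = 0.245 with an estimated correlation. Of the 16 MHC class I and 6 immunoproteasome genes, none passed in limma, at an unadjusted p of 0.05 or adjusted over the list alone (0 genes each, camera adjusted p = 0.725 for both). CIITA fell by 1.24 ± 0.69 (adjusted p = 0.0404), which did not pass without thyroid 1, 3 or 5 (adjusted p = 0.128, 0.104 and 0.170). This addition changed 1938 genes, 877 upward and 1061 downward, with 1228 without thyroid 3 and 1118 without thyroid 4.

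Adding IFN-gamma to IL1-beta raised UBD by 6.74 ± 1.63 (adjusted p = 5.61e-05), CXCL9 by 6.35 ± 2.78 (adjusted p = 0.000279) and CCL8 by 6.24 ± 0.99 (adjusted p = 8.35e-07). The tight junction gene CLDN16 fell by 2.52 ± 0.56 (adjusted p = 0.000723) and the receptor LGR5 by 2.47 ± 0.98 (adjusted p = 0.00148). MHC class II genes rose in 15 of 18 cases (16 adjusted over the list alone), with CIITA up by 3.02 ± 0.84 (adjusted p = 0.000108), a camera adjusted p = 9.28e-18 and adjusted p = 0.0234 with an estimated correlation. IFN-gamma signalling genes and targets rose in 29 of 37 cases and fell in 1 (33 and 1 adjusted over the list alone, and 32 and 1 without the thyroid 2 vehicle and thyroid 4 IL1-beta arrays). For that list the camera adjusted p = 9.91e-27 became adjusted p = 0.0542 with an estimated correlation. Type I interferon genes rose in 20 of 29 cases (27 adjusted over the list alone, 26 without the thyroid 2 vehicle array, 22 without the thyroid 4 IL1-beta array), with a camera adjusted p = 4.88e-16 and adjusted p = 0.295 with an estimated correlation. IL6 (0.48 ± 0.34, adjusted p = 0.420), CCL20 (-0.24 ± 0.30, adjusted p = 0.889), TG (-0.13 ± 0.35, adjusted p = 0.789) and TSHR (-0.38 ± 0.46, adjusted p = 0.190) did not pass. This addition changed 1717 genes, 804 upward and 913 downward, and at least 2-fold changes numbered 274 upward and 123 downward. The count was 1010 without thyroid 3, 1049 without thyroid 4 and 921 without thyroid 5. More genes rose than fell without thyroid 2 (675 and 648), 3 (530 and 480), 4 (547 and 502) or 5 (473 and 448).

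Whether both cytokines together did more or less than the sum of their separate log2 changes was asked by the interaction. CCL8 exceeded the sum by 5.14 ± 0.93 (adjusted p = 0.00137), NOS2 by 3.14 ± 0.57 (adjusted p = 0.00615), the zinc transporter SLC39A8 by 2.56 ± 0.92 (adjusted p = 0.00137) and SLAMF7 by 2.23 ± 0.94 (adjusted p = 0.00697). IRF1 lay below the sum by -2.05 ± 0.56 (adjusted p = 0.0141), PSMB10 by -1.96 ± 0.68 (adjusted p = 0.0141), NRP1 by -1.66 ± 0.45 (adjusted p = 0.00137) and DCBLD2 by -1.64 ± 0.62 (adjusted p = 0.00137). Of these, CCL8, SLC39A8 and DCBLD2 passed whichever thyroid was left out. NOS2 (adjusted p = 0.0821) and NRP1 (adjusted p = 0.0525) did not pass without thyroid 3, nor SLAMF7 without thyroid 4 (adjusted p = 0.0663). Without thyroid 1, 3, 4 or 5, IRF1 (adjusted p = 0.0793, 0.0999, 0.0927 and 0.0778) and PSMB10 (adjusted p = 0.0852, 0.132, 0.0927 and 0.105) did not pass. The offsets understate small changes of dim genes more than large ones. For a gene dim in vehicle this alone can place the combination above the sum. The single changes were 1.10 and 0.81 for CCL8 and 0.39 and 1.59 for NOS2, and other offsets were not tested gene by gene.

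MHC class I genes lay below the sum as a list, with a median of -0.71, as did the immunoproteasome genes (-1.35), the IFN-gamma signalling genes and targets (-0.59) and the type I interferon genes (-0.83). Their camera adjusted p was 1.09e-06, 3.20e-08, 1.09e-06 and 0.000882, and adjusted p = 0.699, 0.248, 0.699 and 0.863 with an estimated correlation. Single members passed below the sum in limma in 0 of 16, 1 of 6, 1 of 37 and 0 of 29 cases (1, 6, 8 and 0 adjusted over the list alone, 9, 6, 13 and 3 at an unadjusted p under 0.05), and without the thyroid 2 vehicle array in 4, 5, 4 and 1. That run kept the IL1-beta array of thyroid 2, which was high too, so its counts are not cleaner estimates. The type I interferon call was lost without the thyroid 4 IL1-beta array (camera adjusted p = 0.115) or without thyroid 4 (0.289). Outside the interferon lists, glycolysis and hypoxia genes also lay below the sum (median -0.25, camera adjusted p = 4.22e-05), and cholesterol synthesis (0.25) and oxidative phosphorylation genes (0.12) lay above it (camera adjusted p = 0.00413 each). With an estimated correlation these became adjusted p = 0.699, 0.708 and 0.699, and no member of these 3 lists passed in limma, also adjusted over the list alone (6 below, 1 above and 1 above at an unadjusted p under 0.05). The cholesterol call was lost without thyroid 5 (0.0711) and the oxidative phosphorylation call without thyroid 1 (0.0589). TG (0.90 ± 0.39, adjusted p = 0.379) and TSHR (0.27 ± 0.71, adjusted p = 0.802) did not pass, and no member of the thyroid function, cell cycle or MHC class II lists passed in limma (2, 0 and 2 at an unadjusted p under 0.05). Without thyroid 1, 2 or 5 the MHC class II list passed below the sum (camera adjusted p = 0.0310, 0.00708 and 0.0192, against 0.0862 with all). These runs kept thyroid 4, where that list's median was -1.42, against -0.34 to 0.30 in the others. The cell cycle list passed above the sum without thyroid 3 (camera adjusted p = 0.0355, against 0.765 with all). Its medians in thyroids 1 to 5 were 1.15, -0.83, -0.93, 0.23 and 0.64.

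Over all genes, 40 departed from the sum, 22 above and 18 below, each in the same direction in all 5 thyroids, and 1310 had an unadjusted p under 0.05. The count was 17, 31, 5, 8 and 8 without thyroids 1 to 5 in turn, and 88 without the thyroid 2 vehicle array. The last run kept the IL1-beta array of thyroid 2, which was high in type I interferon genes too, so 88 is not a cleaner estimate. Fewer lay above than below the sum without thyroid 2 (13 and 18) and without its vehicle array (31 and 57).

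**Figure D5:**
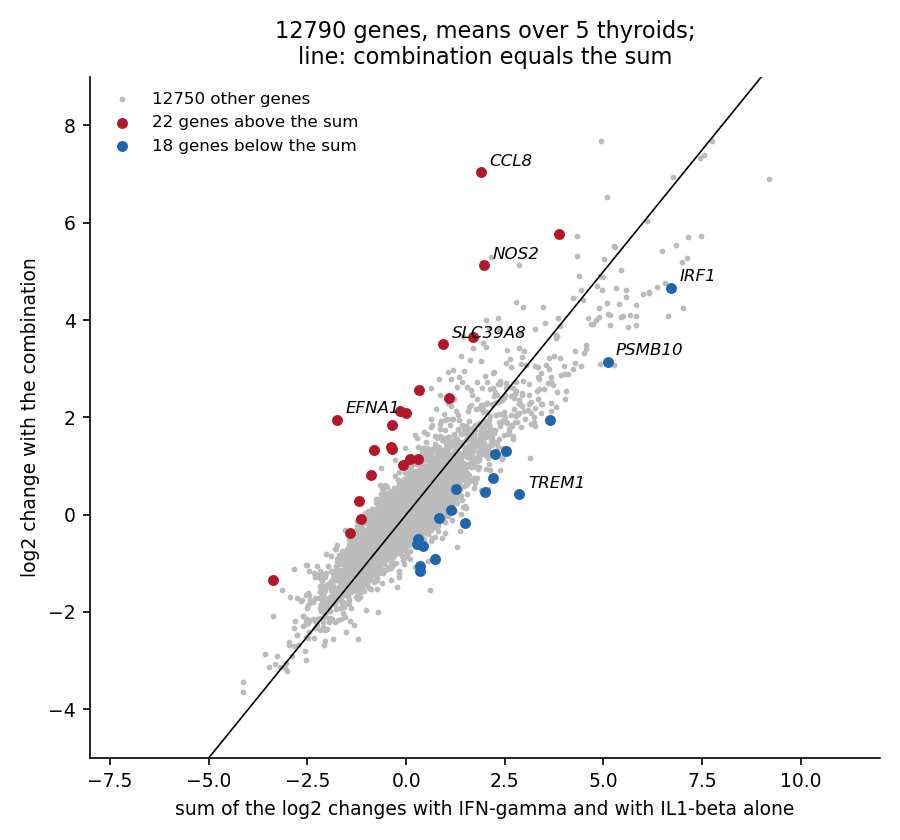
Log2 change with both cytokines (y axis) against the sum of the log2 changes with each alone (x axis), with 1 point per gene for 12790 genes. The 22 genes above and 18 below the sum that passed are coloured, among them CCL8 and NOS2 above and IRF1 and PSMB10 below.

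The separate changes with IFN-gamma and IL1-beta shared direction. Of the genes that passed with each, 249 rose with both cytokines given separately, where independent lists of these sizes would share 55.1, and 358 fell with both (85.2). Another 17 rose with IFN-gamma and fell with IL1-beta (66.0), and 24 did the reverse (71.1). Both changes use the same vehicle arrays, which alone makes them correlate: across genes, which are not independent replicates, their correlation was 0.449, and data simulated with no effect gave 0.499. The covariance was 0.102 against 0.0197 in the simulated data. With IFN-gamma changes from some thyroids and IL1-beta changes from the others, the correlation averaged 0.328 (0.239 to 0.432 over 20 choices of thyroids) and the covariance 0.0868. Of the 4455 genes changed by the combination, 1945 passed with neither cytokine alone, and 14 of these departed from the sum of the 2 cytokines by the interaction test.

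Markers of other cell types were examined in 6 lists. Of 19 T and natural killer cell markers, 1 rose with IFN-gamma, 3 with IL1-beta and 3 with both, also adjusted over the list alone, including IL7R (3.17 ± 0.29 with both, adjusted p = 3.78e-06). With both cytokines that list had a median of -0.012 and a mean of 0.21. Of 13 B and plasma cell markers, 2, 0 and 2 rose (2, 0 and 0 adjusted over the list alone, 0 with IL1-beta at an unadjusted p under 0.05). Of 14 macrophage and dendritic cell markers, 0, 0 and 1 rose, the 1 being FCER1G (0.77 ± 0.32, adjusted p = 0.000316), also adjusted over the list alone, with 2, 2 and 1 at an unadjusted p under 0.05, and of 11 endothelial markers 1, 0 and 1 rose (0, 0 and 1 adjusted over the list alone, 1 with IL1-beta at an unadjusted p under 0.05). The endothelial median and mean with IFN-gamma were -0.032 and 0.02. Of 8 C cell markers, 0, 1 and 2 fell (0, 2 and 2 adjusted over the list alone, 1 with IFN-gamma at an unadjusted p under 0.05), with CALCA down by 0.95 ± 0.56 with both (adjusted p = 0.000452). No member of these 5 lists changed the other way in limma, and their camera adjusted p ranged from 0.224 to 0.630. Of 19 fibroblast and mesenchymal markers, 3 fell with IFN-gamma, 5 fell and 2 rose with IL1-beta, and 7 fell and 2 rose with both (5 fell with IFN-gamma adjusted over the list alone). THY1 fell by 1.93 ± 0.64 (adjusted p = 1.69e-06) and POSTN by 1.76 ± 0.70 (adjusted p = 1.92e-05) with both, and decorin, DCN, rose by 1.58 ± 0.98 with IL1-beta (adjusted p = 0.00215). The camera adjusted p of this list was 0.0188, 0.163 and 0.0758, the lowest being adjusted p = 0.279 with an estimated correlation and 0.141 without thyroid 1. For both cytokines it was 0.0365 without thyroid 4 and 0.0366 without thyroid 5.

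The authors' deposited table calls probe sets by an unadjusted p under 0.01 and a fold above 2. By that rule it holds 541 probe sets for IFN-gamma (379 higher, 162 lower), 722 for IL1-beta (453 and 269) and 1774 for the combination (957 and 817). Against IFN-gamma alone the combination has 696 (455 and 241) and against IL1-beta alone 568 (399 and 169), with 151 in all 3 comparisons of the combination. Recomputing the rule from the 20 arrays over 22277 probe sets gave the same 5 pairs of counts.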

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

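The tests of a wrong label, of mixed RNA and of exchanged arrays, the runs without the vehicle array of thyroid 2 or the IL1-beta array of thyroid 4, and the comparison of the array types were chosen only after the result was seen.

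Of 369 series of 5 within-thyroid changes, for genes and list medians, 36 had 1 thyroid whose gap to its neighbour took a larger part of the range than Dixon's 95% critical value, where chance alone gives about 1 in 20, or 18.4. Of the 36, 18 were thyroid 2, 13 thyroid 4, 3 thyroid 1, 2 thyroid 5 and 0 thyroid 3. The series share arrays and are not independent of each other.

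The IL1-beta array of thyroid 4 held high levels of interferon-regulated genes. With IL1-beta, CXCL9 stood at 6.53 in thyroid 4 (-0.46 to 0.39 in the others), CXCL11 at 5.69 (0.26 to 1.16), CASP1 at 2.06 (0.33 to 0.75), CD74 at 1.43 (-0.56 to -0.16) and the median of the MHC class II list at 0.86 (-0.54 to -0.20). When IFN-gamma was added to IL1-beta, UBD and CXCL9 gained 3.89 and 1.56 there, and the interaction was lowest there for ACSL5 (-2.90) and the type I interferon list (-2.94).

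An IFN-gamma sample under a wrong label is argued against by the MHC class II list, of which 6 of 18 members lay nearer the IFN-gamma array of that thyroid than its vehicle array, against 29 of 29 type I interferon members, and by CCL20, which rose by 7.24. Mixed-in RNA of the IFN-gamma culture would give both lists the same share of their IFN-gamma rise if IL1-beta itself moved neither. The shares were 0.889 (quartiles 0.679 to 1.14) for type I interferon and 0.203 (0.0740 to 0.294) for MHC class II, a ratio of 4.38. In the other thyroids IL1-beta moved the 2 medians by 0.05 to 1.48 and by -0.54 to -0.20. Part of the ratio can come from this, how much was not tested, and mixing is not excluded. A type I interferon made in that culture remains a candidate explanation, since it acts on the type I interferon list more than on MHC class II. Yet IFNB1 changed by 0.59 there and by -0.53 to 0.80 in the others, and a short-lived RNA may be missed. HLA-DRA rose by 1.35 there (-1.56 to -0.59 in the others), while CIITA changed by -0.44 (-1.78 to -0.31). CXCL9 rose by 6.53 there, against 7.13 with IFN-gamma in the same thyroid. These values do not single out a type I interferon. An unlike incubation time for that culture was not tested, as the sources give no time per array. Without the array, 1632 genes passed with IL1-beta, against 1952 with it.

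The vehicle array of thyroid 2 held high levels of type I interferon genes, so that changes from it were small. The IL1-beta array of thyroid 2 was about as high, as the list's median changed by 0.05 from vehicle to IL1-beta. Adding IFN-gamma to IL1-beta moved that median by 0.32 in thyroid 2, against 0.86 to 3.24 in the other thyroids. The high level was thus not confined to the vehicle array. With IFN-gamma, BST2 stood at 0.38, IFI27 at 0.27 (5.42 to 6.48 in the others), TAP1 at 2.36 (4.88 to 5.42) and IFI30 at 2.31 (4.24 to 4.74). With both cytokines, TAP1 stood at 2.35 (4.76 to 5.39), IFI30 at 2.31 and ISG20 at 1.42. Some inflammatory genes also changed less in thyroid 2 than in the others. With IL1-beta, IL6 stood at 3.28 (5.13 to 5.57), SOD2 at 1.22 (4.10 to 4.98) and CXCL1 at 1.11, and with both cytokines IL6 at 3.71, SOD2 at 1.40 and CCL2 at 4.51. Among other genes, BID stood at 1.33, ADM at 1.39, PAX8 at 0.12 and IFNGR1 at -0.054 with IL1-beta.

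On the vehicle array of thyroid 2 the type I interferon list lay 3.66 above the mean of the vehicle arrays of thyroids 1 and 3. PSMB9 lay 3.08 above that mean, while the MHC class II list lay at -0.04 and HLA-DRA at -0.01. An exchange with the IFN-gamma array of thyroid 2 is argued against by the MHC class II list, whose median rose by 2.24 from the vehicle to the IFN-gamma array. Immune cells in the culture are argued against by the medians of their 3 marker lists, the highest of which was 0.0032 above the other vehicle arrays, with PTPRC at -0.16 and CD3D at -0.40, though CD14 lay at 1.11. Earlier contact of the cells of thyroid 2 with a type I interferon may be a source and stays open. However, SOD2 (3.84), CXCL1 (2.63), IL6 (2.49), CXCL10 (2.15) and the medians of the chemokine (0.72) and NF-kB lists (0.57) lay higher on the vehicle array too. That array is therefore not set apart by interferon genes alone. Without the array, 88 genes departed from the sum of the 2 cytokines, against 40 with it. That run kept the high IL1-beta array of thyroid 2, and 31 genes departed when thyroid 2 was left out whole.

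The 22 genes of the MHC class I and immunoproteasome lists lay below the sum of the 2 cytokines, with a median interaction of -0.81. Saturated probe sets are argued against by the 6 members under the 95th percentile of level, whose median was -0.83, while that of the 16 at or over it was -0.81. The 2 arrays above are argued against as the whole cause by thyroids 1, 3 and 5, which hold neither. Their median interactions were -1.12, -0.62 and -0.59 for MHC class I and -1.68, -0.91 and -1.48 for immunoproteasome genes (0.05 and -0.37 in thyroid 2). The median was -0.95 without both arrays, -1.08 without the thyroid 2 vehicle array and -0.66 without the thyroid 4 IL1-beta array. Runs without the vehicle array cannot decide this, since they keep the IL1-beta array of thyroid 2, which was high too. A ceiling of the response once IFN-gamma is present may explain the negative interaction, and was not tested apart from probe saturation. The lists passed with a preset correlation, but their camera adjusted p was 0.699 and 0.248 with an estimated correlation.

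Single genes stood apart elsewhere. With IFN-gamma, CXCL12 (-3.01, others -1.68 to -1.21), PRDX1 (-1.55) and PLAUR (-0.10) did so in thyroid 1, HLA-DMB (1.40) in thyroid 5, RIPK2 (1.81) in thyroid 4 and DSP (-0.18) in thyroid 2. With IL1-beta, TRAF1 (2.46, others 2.87 to 2.99) and ATP5F1A (-0.51) did so in thyroid 4. With both cytokines, CIITA (3.62, others 1.20 to 1.57) did so in thyroid 4 and GFRA2 (-2.26) in thyroid 5.

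The change differed between the U133A arrays (thyroids 1 to 3) and the U133A_2 arrays (thyroids 4 and 5) for 1 gene with IFN-gamma (NRIP3), 1 with IL1-beta (FCMR) and 91 with both cytokines, 48 of them higher on U133A_2. The array type and the thyroids cannot be told apart in this difference, since each thyroid was measured on 1 type. An unadjusted p under 0.05 was reached by 1414, 1246 and 2070 genes.

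Within thyroids, the labels of 2 treatments can be assigned in 16 ways, too few for a share under 0.05. The real assignment was the 1 with the most genes in each comparison, with 1817 genes for IFN-gamma against 0 at most in the others, 1952 against 1 for IL1-beta and 4455 against 418 for both. For IL1-beta added to IFN-gamma it was 1938 against 2, and for IFN-gamma added to IL1-beta 1717 against 1. For the interaction, vehicle was exchanged with IFN-gamma and IL1-beta with the combination at once, and it was 40 against 0. These exchanges also reverse the IFN-gamma effect, which then enters the residual, so the 0 does not measure what chance gives for the interaction. In the first 5 comparisons too, exchanged thyroids keep their real treatment effect, which then enters the residual. The low counts of the other assignments thus do not measure what chance gives there either. In 100 splits of the 10 arrays, drawn without regard to thyroids, the highest others were 404, 237, 1426, 254 and 235 for the first 5 comparisons. The same limit holds for these splits.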

How the results depend on the processing

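The runs without the vehicle array of thyroid 2, without the IL1-beta array of thyroid 4 and without both were chosen only after the result was seen.

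Of 362 named gene changes, 0 turned sign under an alternative if they passed as reported or under it. A change that passed in neither could turn, as TG did with IFN-gamma added to IL1-beta (-0.13, and 0.23 on the U133A_2 arrays alone). Calls were lost for 61 without the thyroid term, 17 with thyroid as a random block, 31, 14, 37, 32 and 29 without thyroids 1 to 5 in turn, 82 on the U133A arrays alone and 83 on the U133A_2 arrays alone, where fewer arrays enter. Calls were lost for 3 with quantile normalization over all arrays, 0 with a common median, and 6, 11 and 12 without the thyroid 2 vehicle array, the thyroid 4 IL1-beta array and both. Without the dimmest 25% or 50% of genes, 355 and 303 of the changes could be tested and 0 lost their call.

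Without 1 thyroid, the count for IFN-gamma was 1068 to 1473, for IL1-beta 1110 to 1666 and for both 3411 to 4153. It was 1118 to 1575 for IL1-beta added, 921 to 1456 for IFN-gamma added and 5 to 31 for the interaction. Fewer arrays enter these runs, which lowers the power.

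Without the thyroid term the counts, in the order IFN-gamma, IL1-beta, IL1-beta added, IFN-gamma added and interaction, were 754, 852, 810, 681 and 11, since differences between thyroids then enter the residual. On the U133A arrays alone they were 657, 895, 774, 485 and 0, and 2589 for both cytokines. On the U133A_2 arrays alone they were 486, 612, 740, 561 and 0. Fitting only the groups of a contrast gave 1078 for IFN-gamma and 1146 for IL1-beta added, with fewer arrays. A fold of at least 1.5, which is a stricter rule, gave 989, 1147, 2553, 1101 and 972 for the 5 treatment comparisons, and an adjusted p under 0.01 gave 853, 955, 953, 836 and 7 in the first order. All 22165 probe sets in place of genes gave 6739 for both cytokines, from a larger number tested.

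With all arrays more genes fell than rose in the 5 treatment comparisons. The balance turned at a fold of at least 1.5 for IFN-gamma (514 up, 475 down), IL1-beta (605, 542), IL1-beta added (588, 513) and IFN-gamma added (552, 420), and at an adjusted p under 0.01 for IFN-gamma (445, 408) and IFN-gamma added (453, 383). It turned without the thyroid term (409 and 345, 448 and 404, 445 and 365, 392 and 289) and on the U133A_2 arrays alone (321 and 165, 355 and 257, 403 and 337, 339 and 222) for these 4 in that order. On the U133A arrays alone it turned for IFN-gamma (306 down of 657) and IFN-gamma added (279, 206), and with only the groups of the contrast for IL1-beta added (582, 564). For both cytokines more fell than rose in all alternatives run.

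For the interaction, an offset of 16 gave 14, a plain 2-way ANOVA 11 after adjustment and 398 at an unadjusted p of 0.01, and trended robust moderation 63, and the cause was not tested. Without the thyroid 2 vehicle array, a run that kept the high IL1-beta array of thyroid 2, it was 88, and 31 without thyroid 2 as a whole. More lay below than above the sum without the dimmest 50% of genes (27 and 18), in the plain ANOVA at an unadjusted p of 0.01 (205 and 193) and without both arrays (31 and 19). Of 174 list tests, 85 passed with the preset correlation, 19 with an estimated one, 82 with fry, and 80 to 89 under the other alternatives.

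Values from the workbook equal those used within 1e-08, so that alternative is identical. Intensities near the offset set the lower limit, with 1.19 to 2.30% of probe sets at the lowest possible value, and changes of dim genes are understated.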

Other observations

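The counts without the vehicle array of thyroid 2 or the IL1-beta array of thyroid 4 were chosen only after the result was seen.

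Cholesterol synthesis genes fell with IFN-gamma in 9 of 18 cases (12 adjusted over the list alone), with a median of -0.51, a camera adjusted p = 4.39e-06 and adjusted p = 0.212 with an estimated correlation. DHCR7 fell by 0.99 ± 0.35 and SQLE by 0.84 ± 0.29. With IL1-beta 3 rose and 1 fell (camera adjusted p = 0.0102, 0.396 with an estimated correlation, 0.0837 without thyroid 2 and 0.0638 without both arrays), INSIG1 rising by 1.46 ± 0.69, and with both cytokines 2 rose and 2 fell, and the list did not pass in camera.

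Oxidative phosphorylation genes fell in 14, 9 and 17 of 27 cases with IFN-gamma, IL1-beta and both (20, 14 and 19 adjusted over the list alone), and 1 rose with both. For IL1-beta the count was 7 without the thyroid 2 vehicle array, 6 without the thyroid 4 IL1-beta array and 4 without both. The medians were -0.35, -0.26 and -0.41, the camera adjusted p 5.01e-09, 3.28e-05 and 1.26e-06, and adjusted p = 0.0843, 0.189 and 0.111 with an estimated correlation. ATP5F1A fell by 0.71 ± 0.08 with both cytokines (adjusted p = 6.12e-06).

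Glycolysis and hypoxia genes rose in 5, 9 and 12 of 22 cases and none fell, also at an unadjusted p under 0.05 (7, 12 and 12 rose adjusted over the list alone). Camera gave an adjusted p of 0.000246, 3.26e-08 and 8.81e-05, and adjusted p = 0.419, 0.212 and 0.350 with an estimated correlation. Adrenomedullin, ADM, rose by 2.38 ± 1.16, 3.19 ± 1.04 and 4.63 ± 1.33, and HK2 by 1.28 ± 0.44 with IL1-beta.

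Of 18 oxidative stress and metallothionein genes, 0 rose and 1 fell with IFN-gamma in limma (4 and 4 adjusted over the list alone, 6 and 5 at an unadjusted p under 0.05), 6 rose and 5 fell with IL1-beta, and 8 rose and 6 fell with both. For both cytokines the list's median (-0.0064) and mean (-0.08) were negative while the camera test pointed upward, as for IL1-beta (-0.010 and -0.03). MT1G rose by 1.20 ± 0.20 with both (adjusted p = 5.16e-07). Of 18 unfolded protein response genes, 5, 2 and 4 rose and 0, 0 and 2 fell (6, 1 and 4 and 2, 0 and 2 adjusted over the list alone, with 4, 0 and 2 falling at an unadjusted p under 0.05), and ATF3 rose by 2.71 ± 0.64, 1.07 ± 0.40 and 3.70 ± 0.44. Of 18 TGF-beta family genes, none changed with IFN-gamma in limma (1 rose at an unadjusted p under 0.05), 3 rose and 3 fell with IL1-beta, and 4 rose and 7 fell with both (8 fell adjusted over the list alone). None of these 3 lists passed in camera with all thyroids, the lowest adjusted p being 0.0818. The unfolded protein response list passed with IFN-gamma without thyroid 4 (0.0413) and with IL1-beta without thyroid 4 (0.0447) or thyroid 5 (0.0282).

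Of 24 constitutive proteasome genes, 4 rose and 3 fell with IFN-gamma, 5 rose with IL1-beta, and 6 rose and 3 fell with both (4 fell with IFN-gamma adjusted over the list alone). Camera gave an adjusted p of 0.681, 0.00836 and 0.208, the second being adjusted p = 0.396 with an estimated correlation and 0.0773 without both of the arrays named above. With both cytokines the median was -0.013 and the mean 0.09, the test pointing upward. PSMA4 rose by 0.86 ± 0.09 with IFN-gamma.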
